A study of Mus musculus with 7 samples.

How the data were processed

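Polyadenylated RNA was measured in 7 tissue sections of mouse tibialis anterior and extensor digitorum longus muscle with Visium, an assay in which a frozen section is laid on a slide printed with barcoded spots and each captured transcript is counted once by its unique molecular identifier (UMI). The muscles had been embedded in OCT and flash frozen, per the labels' protocols. The authors deposited UMI counts per gene and spot, not normalised, with 32285 genes in every section and with spot positions. Counts came from Space Ranger on the mm10 build, per the submitters' processing notes. The count files name Space Ranger 1.1.0 for 4 sections and 2.1.1 for the other 3, per the file headers. The listed spots were those the authors' software had placed under tissue, out of 4992 per capture area. Filters and annotation release beyond this are not given in the sources used here.

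Sections were grouped by the genotype and age in the labels. There was 1 wild type (C57BL/6J) section at 75 d and 1 at 150 d, 3 SOD1G93A sections at 75 d and 2 at 150 d. The SOD1G93A sections of a group are called biological replicates in their titles. The labels also carry 2 identifiers, ID2237 and ID3215, which split the sections in the same way as the Space Ranger versions and are called the first and the second batch here. The first batch held 4 sections, among them both wild type sections, replicate 1 of SOD1G93A at 75 d and replicate 1 at 150 d. The second batch held 3 sections, replicates 2 and 3 at 75 d and replicate 2 at 150 d. No pair of replicates was a duplicate, since the chi-square per degree of freedom between replicate counts ran from 14.1 to 49.4.

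Spots with fewer than 500 UMIs were dropped, which removed 2 spots and kept 5286. Counts were summed over the kept spots of each section, because spots are not replicates. Section totals ran from 5042893 to 16878027 UMIs, so that a count of 0 allowed a level of up to 0.178 to 0.595 CPM (UMIs per library scaled to 1e6) for 3 counts. Intervals and floors cover counting error only. Symbols carried by more than 1 feature (78 features) were kept as separate features. Coordinates of named genes were taken from NCBI's gene table for GRCm38.p6, the assembly behind mm10.

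The 13125 genes that passed filterByExpr were tested with edgeR 4.0.16 (TMM normalisation, glmQLFit and glmQLFTest, R 4.3.3) in 1 fit of all 7 sections with a term for each group and a term for the batch, which left 2 residual degrees of freedom. The wild type groups had 1 section each, so the residual spread came from the SOD1G93A sections alone and each wild type section was assumed to vary like them. The contrasts were SOD1G93A at 150 d against 75 d, SOD1G93A against wild type at each age and averaged over ages, and the interaction of genotype and age. A gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Values after ± are the standard error (SE) for a fitted log2 change and the standard deviation (SD) over sections for a CPM; CPM are after TMM scaling. TMM factors ran from 0.709 to 1.22. Scaling to library size alone would move the median gene by 0.18 to 0.75 on the log2 scale across these contrasts, and changes are stated relative to the TMM scale.

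Areas within sections were compared in the same way on counts summed per section and area, with the section as a block. For the first area contrast, spots with at least 10 UMIs of Myh1, Myh2, Myh4 and Myh7 were ranked within each section. The rank was by the share of Myh4 among these, and the upper tertile (Myh4-rich) was set against the lower (Myh4-poor). These 4 genes were left out, and 11590 genes were tested with 3 residual degrees of freedom. An area effect was fitted for each of the 4 groups, and these were averaged with equal weights. Each single wild type section thus weighs as much as a whole SOD1G93A group, and the residual spread comes from the SOD1G93A sections alone. For the second, each spot was taken with its up to 6 neighbours and ranked by the share of UMIs from the denervation response list, and the top 20% of spots were set against the lower 50%; the genes of that list were left out, and 11742 genes were tested with 5 residual degrees of freedom. The areas are ranges of a score, not cell types: from 193 to 362 spots per section lay within 5 percentage points of a tertile boundary of the Myh4 share.

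Shifts of 30 gene lists (20 pathways or gene groups and 10 sets of cell type markers) were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with adjustment over the lists. Camera with an estimated correlation and fry were run beside it. With an estimated correlation camera rests on the few residual degrees of freedom of the fit and has little power. A list that fails it is thus not shown to be unshifted. For each list the counts of members past the threshold are given over all genes tested and adjusted over the list alone. Spatial patchiness was described with Moran's I of the share of UMIs from a list, over adjacent spots thinned to 1000 UMIs. Shares of spots with a UMI of a gene carry exact (Clopper-Pearson) 95% intervals. The wild type sections of the 2 ages were compared by value only, without a test.

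The tests, lists, spot filter, alternatives and the rule for naming genes were fixed before the data were examined. The rule took, per comparison, the 8 largest rises and 8 largest falls past the threshold with an average log2 CPM of at least 5 and the same sign in both batches or every section; up to 4 members of each list past the threshold; and Sod1, Odc1, Amd1, Smox, Sat1, Srm, Sms, Myh1, Myh2, Myh4, Myh7, Chrna1, Myog, Fbxo32 and Trim63 whatever their result. It selected 620 pairs of a gene and a comparison. For length, 332 pairs, of which 1 gene in 1 comparison lies outside the rule, were examined under every alternative, 284 of them past the threshold, and the text names only part of these. Genes with 3 or fewer UMIs on 1 side of a comparison were given no fitted fold. For a reason other than length, results of 2 genes that the rule selected are not reported. The alternatives were DESeq2 1.42.0 in place of edgeR, RLE size factors, no gene filter, no batch term, the replicate number as a block, stricter and looser spot filters, mitochondrially encoded genes left out, other boundaries of the areas, and each section left out in turn. Other splits of the samples were not counted, because no comparison of whole sections had 3 sections on both sides and the areas, which have every section on both sides, were defined from the data.

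The procedure was tested on simulated counts with the real means and depths, a batch effect with an SD of 0.3 on the log2 scale and 200 changed genes. The batch effect was put into the counts of whole sections only. For the areas no batch or section effect was simulated, nor the choice of the areas from the counts, so their setting was easier than the data. At a log2 change of 2 it recovered 93% of the changed genes for SOD1G93A at 150 d against 75 d, 72% and 82% for SOD1G93A against wild type at 75 d and 150 d, 95% for the average over ages and 48% for the interaction. At a log2 change of 1 the values were 62%, 9%, 15%, 57% and 4%. False calls made up 19 of 174, 1 of 82, 9 of 106, 26 of 178 and 8 of 60 calls in that order, so that the simulated share of false calls exceeded the nominal level for all of these but SOD1G93A against wild type at 75 d. For Myh4-rich against Myh4-poor areas 95% were recovered at a log2 change of 2, with 10 false calls of 175, and for areas rich in denervation transcripts 96%, with 12 of 181. Differences of an area effect between groups were recovered in 77% for genotype in the Myh4 areas, 81% for age and 77% for genotype in the denervation areas, with 2 of 119, 6 of 118 and 7 of 107 calls false. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used for reading, scoring and thinning, and matplotlib 3.10.9 for the plots.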

Results

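The series concerns polyamines and the vulnerability of muscle fibres in amyotrophic lateral sclerosis (ALS). The labels describe hindlimb muscle (tibialis anterior with extensor digitorum longus) of mice that carry a mutant human SOD1 transgene, SOD1G93A, which causes motor neuron loss and paralysis, and of wild type mice, at 75 d and 150 d of age. Transcripts were counted at barcoded spots across 7 sections: 1 wild type section at 75 d, 1 wild type section at 150 d, 3 SOD1G93A sections at 75 d and 2 SOD1G93A sections at 150 d. After the spot filter the wild type sections held 9305116 UMIs at 75 d and 9543234 at 150 d. The SOD1G93A sections held 16878027, 7370359 and 10936706 UMIs at 75 d (replicates 1 to 3) and 9254514 and 5042893 UMIs at 150 d (replicates 1 and 2). The median spot held 7094 and 9790 UMIs in wild type at 75 d and 150 d, from 11283.5 to 17844.5 in SOD1G93A at 75 d, and 17798.5 and 7978.5 at 150 d. The 2 muscles were not separated.

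The labels were checked on Sod1 itself. Sod1 stood at 248 and 231 CPM in wild type at 75 d and 150 d, against 1947 ± 654 (SD, n = 3) and 2516 ± 1392 (SD, n = 2) in SOD1G93A. Whether reads of the human transgene were counted on mouse Sod1 was not tested, so this difference is a check of genotype and not a measure of the mouse gene. Xist, a transcript of the inactive X chromosome of females, had 386 UMIs in SOD1G93A replicate 2 at 150 d and 0 or 1 in the other 6 sections. Ddx3y, a Y chromosome gene, had 2 UMIs in that section and from 540 to 1119 in the others. The labels give no sex, so within SOD1G93A at 150 d these genes and the replicate go together.

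SOD1G93A was first set against wild type at 75 d, at 150 d and averaged over both ages, which asks which transcripts differ in diseased muscle. Genes that muscle fibres switch on when they lose their nerve were far higher in SOD1G93A at both ages. Chrna1, a subunit of the acetylcholine receptor, stood at 11.7 CPM in wild type and 252 ± 49.9 (SD, n = 3) in SOD1G93A at 75 d, and at 10.9 and 291 ± 84.1 (SD, n = 2) at 150 d. Myog, a myogenic transcription factor, went from 1.02 to 85.8 ± 32.6 CPM at 75 d and from 1.33 to 112 ± 22.9 at 150 d. At 75 d Ankrd1, a stretch-responsive nuclear protein, rose from 4.06 to 481 ± 40.1 CPM, Rrad, a small GTPase, from 1.52 to 239 ± 98.8, Igfn1 from 2.16 to 160 ± 10.7 and Runx1, a transcription factor of denervated fibres, from 2.41 to 133 ± 44.4. Krt8, a keratin, was at least 123-fold higher at 75 d and at least 597-fold higher at 150 d, against a floor of 3 counts in the wild type section, and Krt18, its partner, at least 352-fold higher at 75 d. Chrng, the fetal receptor subunit with 1 UMI in each wild type section, was 313 times as high at 75 d (counting interval 56.1 to 12348) and 190 times at 150 d (34.2 to 7521).

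By edgeR the log2 change at 75 d was 4.41 ± 0.45 (SE, adjusted p = 0.00303) for Chrna1, 6.04 ± 0.68 (0.00475) for Myog and 5.50 ± 0.56 (0.00303) for Runx1, and at 150 d 4.72 ± 0.45 (0.00107), 6.21 ± 0.65 (0.00165) and 5.47 ± 0.55 (0.00134). Cpne2, a calcium-binding protein, rose by 5.20 ± 0.37 at 75 d (adjusted p = 0.000754). Of the 22 genes of the denervation response list, 17 rose at 75 d (19 adjusted over the list alone) and 20 at 150 d (20 adjusted over the list alone), and none fell. The camera adjusted p was 9.46e-66 and 5.54e-51, and the adjusted p was 0.542 and 0.387 with an estimated correlation. Averaged over ages 20 rose (camera adjusted p = 1.24e-67, and adjusted p = 0.284 with an estimated correlation). Within the first batch alone, where both wild type sections lay, Chrna1 stood at 197 CPM in SOD1G93A at 75 d and 350 at 150 d. The second batch held no wild type section.

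**Figure D1:**
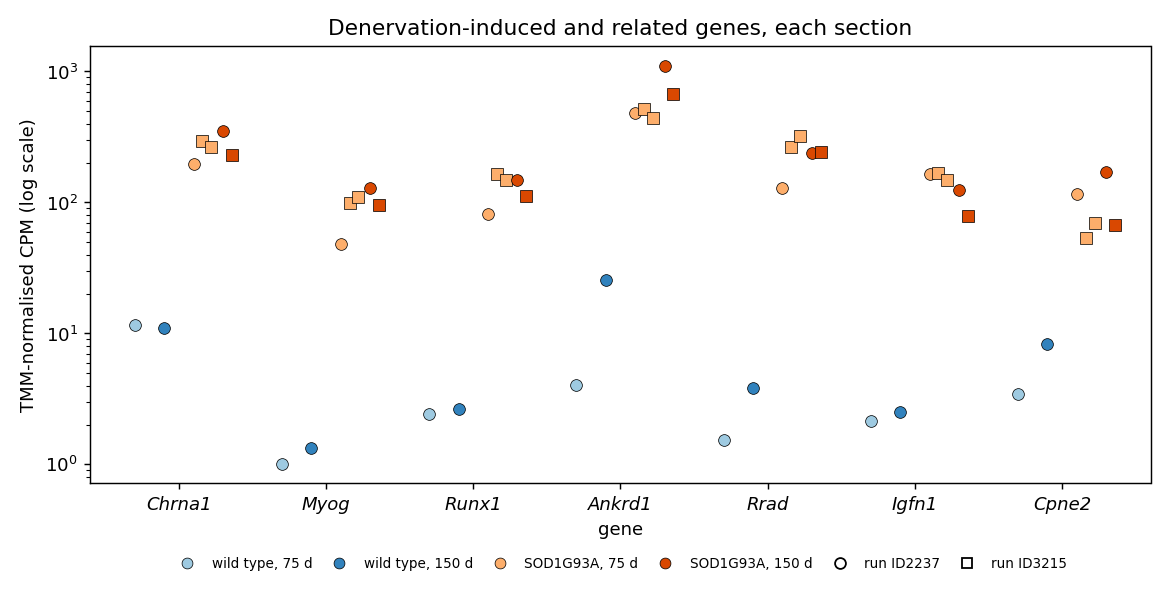
TMM-normalised CPM on a log axis for 7 genes of denervated muscle, 1 point per section, with circles for the first batch and squares for the second. Chrna1 lies at 10.9 and 11.7 in wild type and between 197 and 350 in SOD1G93A.

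Among polyamine genes the change was split by enzyme. Amd1 (ENSMUSG00000075232, chromosome 10, 40287458 to 40302188 on mm10), which makes the aminopropyl donor for spermidine and spermine, stood at 119 CPM in wild type and 22.5 ± 11.1 (SD, n = 3) in SOD1G93A at 75 d, and at 102 and 8.35 ± 0.273 (SD, n = 2) at 150 d. Smox (ENSMUSG00000027333, chromosome 2, 131491858 to 131525183), which oxidises spermine back to spermidine, stood at 81.0 CPM in wild type and 11.7 ± 3.33 in SOD1G93A at 150 d. Odc1 (ENSMUSG00000011179, chromosome 12, 17544808 to 17551502), which makes putrescine at the start of the pathway, rose from 44.6 to 127 ± 9.28 CPM at 75 d and from 45.4 to 145 ± 22.5 at 150 d. Amd2 (ENSMUSG00000063953, chromosome 10, 35708691 to 35711891), a near-identical copy of Amd1, fell from 18.7 to 3.5 ± 1.45 CPM at 75 d and from 13.9 to 1.86 ± 0.246 at 150 d. Whether a read of one copy was counted on the other was not tested at the level of reads, so the separate levels of Amd1 and Amd2 are uncertain.

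The log2 change of Amd1 was -1.98 ± 0.32 at 75 d (edgeR adjusted p = 0.022), -3.27 ± 0.35 at 150 d (0.00174) and -2.62 ± 0.27 averaged over ages (0.000849). Odc1 rose by 1.66 ± 0.25 (0.0152), 1.78 ± 0.25 (0.00625) and 1.72 ± 0.18 (0.00103). Smox changed by -2.24 ± 0.40 at 150 d (0.0138) and -1.57 ± 0.30 averaged over ages (0.0104), while its value at 75 d, -0.91 ± 0.36, did not pass (0.222). Sat1, which acetylates polyamines for export, and the synthases Srm and Sms did not pass averaged over ages (log2 values 0.30, 0.65 and 0.33, adjusted p = 0.32, 0.115 and 0.246). Of the 27 measured polyamine genes 1 rose and 2 fell at 75 d (1 and 2 adjusted over the list alone), and 1 rose and 3 fell at 150 d (1 and 3 adjusted over the list alone). The list as a whole did not shift at 75 d or 150 d (camera adjusted p = 0.713 and 0.586).

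Within the first batch Amd1 stood at 34.9 CPM at 75 d and 8.54 at 150 d in SOD1G93A, and Smox at 77.5 and 14.1. In the second batch, which held no wild type section, Amd1 stood at 13.6 and 18.9 CPM at 75 d and 8.16 at 150 d, and Smox at 18.8, 32.5 and 9.35. Schwann cell and endothelial markers moved down beside Amd1 and Smox at 150 d, with 5 of 9 and 4 of 10 past the threshold as lower. Some macrophage and tendon markers rose instead, as given below. Without SOD1G93A replicate 3 at 75 d, Odc1 at 75 d (1.64) was no longer past the threshold, nor was it under the replicate block (1.65). Smox at 75 d passed without the gene filter (-0.87) and without SOD1G93A replicate 1 at 75 d (-1.7). Without SOD1G93A replicate 1 or 2 at 150 d its value at 75 d was -0.70. With the batch term both of these fits set SOD1G93A replicate 1 at 75 d alone against wild type, so they are not separate results.

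**Figure D2:**
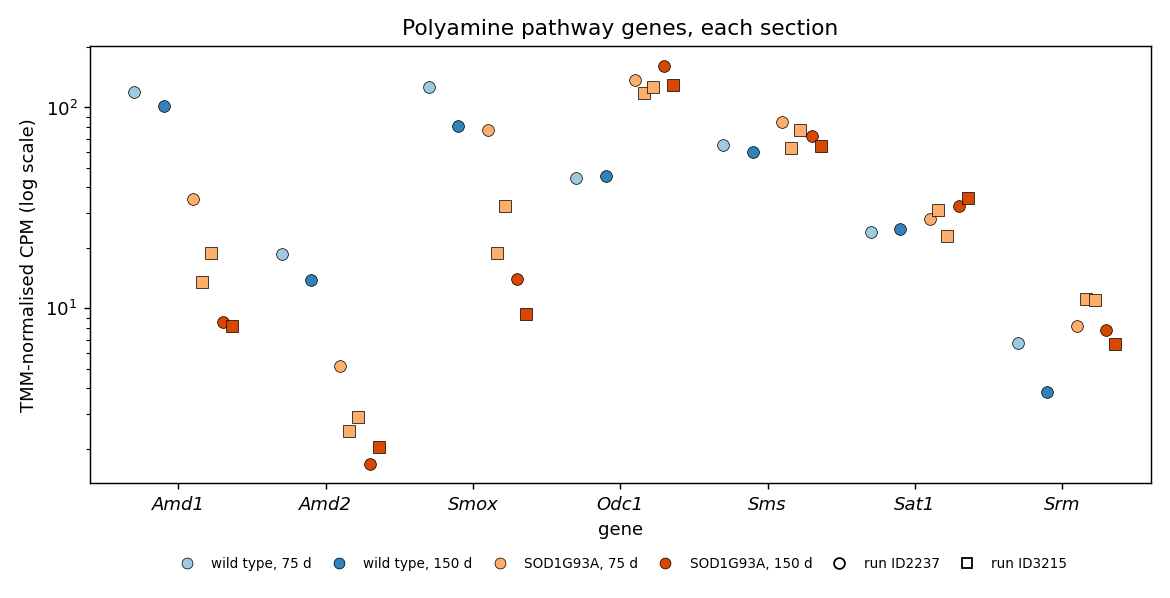
TMM-normalised CPM on a log axis for 7 polyamine genes, 1 point per section, with circles for the first batch and squares for the second. Amd1 lies at 102 and 119 in wild type and between 8.16 and 34.9 in SOD1G93A, while Odc1 lies at 44.6 and 45.4 in wild type and between 118 and 161 in SOD1G93A.

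Myosin heavy chain genes mark muscle fibre types, with Myh7 in slow fibres, Myh2 and Myh1 in faster oxidative fibres and Myh4 in the fastest glycolytic fibres. Myh4 made up 71.2% and 63.4% of the UMIs of these 4 genes in wild type at 75 d and 150 d. In SOD1G93A it made up 68.8%, 45.2% and 58.2% at 75 d and 27.4% and 28.4% at 150 d. The Myh2 share was 2.16% and 3.33% in wild type, from 1.86% to 4.45% in SOD1G93A at 75 d, and 20.5% and 21.9% at 150 d. At 150 d Myh2 rose by 1.86 ± 0.33 on the log2 scale against wild type (edgeR adjusted p = 0.0142), Myh7 by 7.21 ± 0.52 (0.000714) from 4 UMIs in wild type, and Sln, which slows the calcium pump, by 8.29 ± 0.65 (0.000714). Tnni1 and Tnnt1, troponins of slow fibres, rose by 5.44 ± 0.43 and 4.46 ± 0.37, and Myl2, a slow light chain, by 4.45 ± 0.61. Myh3, the embryonic myosin, rose from 1.03 to 117 ± 22.6 CPM at 150 d. Of the 12 slow fibre genes 10 rose at 150 d (11 adjusted over the list alone) and 1 rose at 75 d (4 adjusted over the list alone), with a camera adjusted p of 8.77e-28 at 150 d (adjusted p = 0.213 with an estimated correlation) and 0.0521 at 75 d. Myh4 (-1.49 ± 0.55, adjusted p = 0.124) and Myh1 (-0.03, 0.974) did not pass at 150 d. Of the 14 fast fibre genes 1 fell at 150 d, Mybpc2, a fast myosin-binding protein (-1.89 ± 0.50, 0.0487; 0 adjusted over the list alone), with a camera adjusted p of 0.0169 and an adjusted p of 0.741 with an estimated correlation. The Myh2 call at 150 d was lost without SOD1G93A replicate 3 at 75 d (1.90), where Mybpc2 was lost too (-1.81), and under the replicate block (1.89 for Myh2). Mybpc2 was also lost under the block (-1.82), in DESeq2 (-1.89), with RLE size factors (-1.89), without the mitochondrially encoded genes (-1.89) and without SOD1G93A replicate 1 at 150 d (-0.98), where the shift of the fast fibre list was lost as well (camera adjusted p = 0.723). Myh4 passed at 150 d without the gene filter (-1.45), without SOD1G93A replicate 1 at 75 d (-1.89) and without replicate 2 at 150 d (-1.88). The latter fits both set replicate 1 at 150 d alone against wild type, so they are not separate results.

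**Figure D3:**
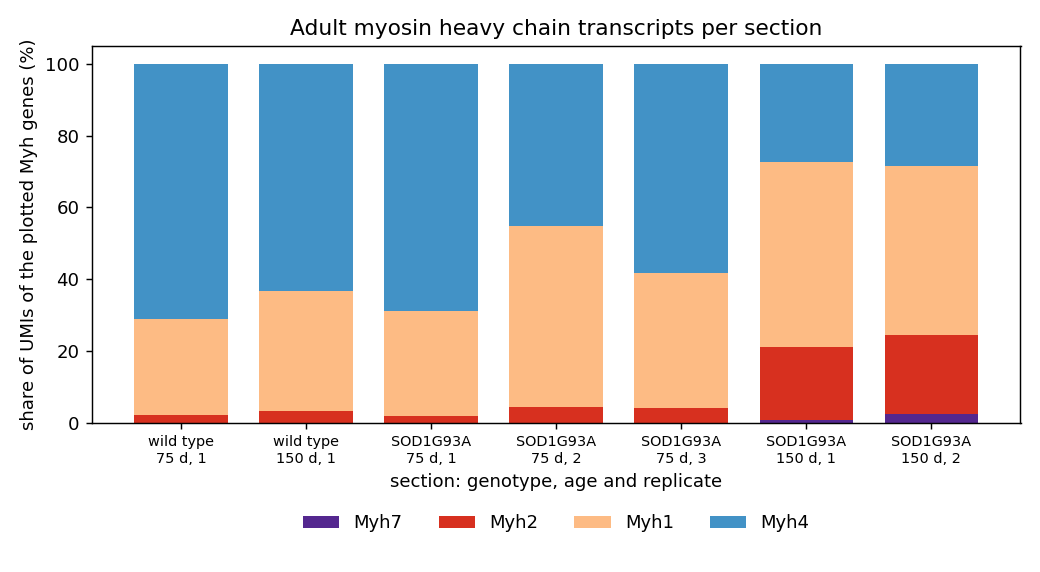
Stacked bars of the percentage of Myh7, Myh2, Myh1 and Myh4 among the UMIs of these 4 genes, 1 bar per section. Myh2 takes 20.5% and 21.9% in SOD1G93A at 150 d and at most 4.45% in the other sections.

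Some mitochondrial and metabolic transcripts were lower in SOD1G93A. mt-Atp8, a mitochondrially encoded ATP synthase subunit, stood at 8628 CPM in wild type and 677 ± 96.8 in SOD1G93A at 150 d (log2 -3.48 ± 0.44, edgeR adjusted p = 0.00432), and mt-Nd4l, a complex I subunit, at 3996 and 536 ± 82.9 (-2.74 ± 0.36, 0.00538). mt-Nd6, another complex I subunit, fell by 1.53 at 75 d (adjusted p = 0.0153). The nuclear genes Cox7b, Uqcrb and Cycs of the respiratory chain fell by 1.69 ± 0.33, 1.67 ± 0.35 and 1.64 ± 0.34 at 150 d, and Cd36, a fatty acid transporter, by 1.09 ± 0.24. Pfkfb3, which drives glycolysis, fell from 100 to 21.0 ± 2.06 CPM at 75 d (0.0152), and Ppp1r3a, which targets a phosphatase to glycogen, from 304 to 86.6 ± 23.4 (0.0382).

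At 150 d, 5 of 13 mitochondrially encoded mRNAs fell and none rose (13 adjusted over the list alone; median log2 -1.69, camera adjusted p = 1.68e-18, and adjusted p = 0.539 with an estimated correlation). Of 48 oxidative phosphorylation genes 7 fell (22 adjusted over the list alone; camera adjusted p = 1.26e-12, and adjusted p = 0.735 with an estimated correlation). Of 19 glycolysis genes 1 fell (1 adjusted over the list alone; 0.000188, and adjusted p = 0.741 with an estimated correlation), and of 20 fatty acid oxidation genes 1 fell (5 adjusted over the list alone; 0.0053, and adjusted p = 0.735 with an estimated correlation). At 75 d 1 mitochondrially encoded mRNA fell (3 adjusted over the list alone; 1.21e-05, and adjusted p = 0.637 with an estimated correlation) and 0 oxidative phosphorylation genes (0 adjusted over the list alone; 2.9e-06, and adjusted p = 0.896 with an estimated correlation). Mitochondrially encoded genes took 32.8% and 42.6% of all UMIs in wild type and from 19.4% to 25.7% in SOD1G93A. Without SOD1G93A replicate 3 at 75 d, Cox7b (-1.65) at 150 d and Ppp1r3a (-1.63) at 75 d were lost, as were Uqcrb, Cycs and Cd36. Without SOD1G93A replicate 1 at 150 d, Uqcrb (-1.12), Cycs (-1.09) and Cd36 (-0.99) were lost, and Cycs was lost without a batch term. The glycolysis and fatty acid oxidation shifts at 150 d were also lost without that section (camera adjusted p = 0.875 and 0.0974), and Cox7b, Uqcrb, Cycs, Cd36 and, at 75 d, Ppp1r3a were lost under the replicate block.

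Some genes of protein breakdown rose at 75 d or 150 d. At 75 d Psmd11, a proteasome lid subunit, rose by 1.47 ± 0.27 on the log2 scale (edgeR adjusted p = 0.034), and the autophagosome proteins Map1lc3a by 1.45 ± 0.29 (0.0467) and Gabarapl1 by 1.1 ± 0.23 (0.049). Fbxo32, a ubiquitin ligase of muscle atrophy, rose from 93.4 to 162 ± 23.0 CPM at 150 d (log2 1.06 ± 0.27, edgeR adjusted p = 0.0454), and Trim63, another, rose averaged over ages (1.30 ± 0.26, 0.014) and did not pass at 150 d alone (1.18 ± 0.36, 0.0734). Trim63 did pass at 150 d in DESeq2 (1.18), without the gene filter (1.22), without SOD1G93A replicate 1 (0.86) or 2 (1.12) at 75 d and without replicate 1 (1.87) or 2 (0.86) at 150 d. The fits without replicate 1 at 75 d and without replicate 2 at 150 d both set replicate 1 at 150 d alone against wild type. They are not separate results. Map1lc3a rose from 244 to 758 ± 108 CPM at 150 d (1.77 ± 0.30, 0.0112), with the autophagy receptor Sqstm1 (1.5 ± 0.28) and Gabarapl1 (1.33 ± 0.23). Psmd11 and Psmd13, another lid subunit, rose by 1.32 and 1.17 at 150 d. Of 14 ubiquitin ligases of atrophy 4 rose at 150 d (6 adjusted over the list alone; camera adjusted p = 0.00456, and adjusted p = 0.539 with an estimated correlation), of 31 proteasome genes 5 (6 adjusted over the list alone; 0.00287, and adjusted p = 0.741 with an estimated correlation), and of 19 autophagy genes 4 (6 adjusted over the list alone; 0.00456, and adjusted p = 0.594 with an estimated correlation); none fell. Without a batch term, and without SOD1G93A replicate 3 at 75 d, Fbxo32, Psmd11, Psmd13 and Sqstm1 were lost at 150 d, with Gabarapl1 in the former fit and Map1lc3a (1.82) in the latter. Under the replicate block Fbxo32, Psmd11, Psmd13, Sqstm1 and Map1lc3a were lost.

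At 75 d 0 of the 14 ubiquitin ligases rose (5 adjusted over the list alone; camera adjusted p = 0.0475, and adjusted p = 0.637 with an estimated correlation), 1 of the 31 proteasome genes (5 adjusted over the list alone; 6.09e-05, and adjusted p = 0.896 with an estimated correlation) and 2 of the 19 autophagy genes (5 adjusted over the list alone; 0.00323, and adjusted p = 0.637 with an estimated correlation). Without SOD1G93A replicate 1 at 75 d these shifts were lost (0.235, 0.174 and 0.103), that of the ligases also without replicate 3 at 75 d (0.0554), under the replicate block (0.0567) and without a batch term (0.31), and that of autophagy without a batch term (0.0676). Psmd11, Map1lc3a and Gabarapl1 at 75 d were lost without a batch term (0.96, 1.26 and 0.83). They were also lost without SOD1G93A replicate 3 at 75 d (1.48, 1.41 and 1.11), a fit that the replicate block repeats (1.48, 1.41 and 1.11). With RLE size factors Map1lc3a (1.44) and Gabarapl1 (1.1) were lost, and Gabarapl1 in DESeq2 (1.1).

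Stress genes were higher in part. Srxn1, an antioxidant enzyme, rose by 2.02 ± 0.29 at 75 d (edgeR adjusted p = 0.0134) and 1.75 ± 0.28 at 150 d (0.0102), Hspa1b, a heat shock protein, by 2.94 ± 0.48 at 75 d (0.0228), and Junb, an immediate early factor, by 2.61 ± 0.45 at 150 d (0.013). Fosb, another such factor, stood at 13.9 CPM in wild type at 150 d and 0.0445 ± 0.0629 in SOD1G93A. Of 12 metallothionein and oxidative stress genes 3 rose at 150 d (3 adjusted over the list alone; camera adjusted p = 0.0147, and adjusted p = 0.594 with an estimated correlation). Of 10 immediate early and heat shock genes 2 rose and 1 fell at 150 d (5 and 2 adjusted over the list alone; camera adjusted p = 0.68). At 75 d 2 of them rose and 0 fell (5 rose adjusted over the list alone; 6.09e-05, and adjusted p = 0.637 with an estimated correlation), and averaged over ages 5 rose and 1 fell (5 and 1 adjusted over the list alone; 0.0162, and adjusted p = 0.786 with an estimated correlation; lost without SOD1G93A replicate 1 at 150 d, 0.104). Of the 12 metallothionein and oxidative stress genes 1 rose at 75 d (4 adjusted over the list alone; 0.000175, and adjusted p = 0.637 with an estimated correlation). None of the 15 integrated stress response genes (camera adjusted p = 0.0926), 10 unfolded protein response genes (0.466) or 18 interferon genes (0.2) passed at 150 d.

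Transcripts that mark other cells of the muscle moved in different directions. Prx and Mbp, proteins of the myelin of Schwann cells, were lower in SOD1G93A at 150 d, with Prx at a log2 change of -3.85 ± 0.63 (edgeR adjusted p = 0.0105) and Mbp at 97.4 CPM in wild type and 11.2 ± 3.57 in SOD1G93A (-2.91 ± 0.45, 0.00862). Of 9 Schwann cell markers 5 fell at 150 d (7 adjusted over the list alone; camera adjusted p = 3.87e-09, and adjusted p = 0.539 with an estimated correlation). The endothelial genes Kdr and Vwf fell by 1.39 ± 0.22 and 1.28 ± 0.24 at 150 d, 4 of 10 endothelial markers fell (7 adjusted over the list alone; 6.91e-05, and adjusted p = 0.594 with an estimated correlation), and none of either list rose. At 75 d 0 Schwann cell markers fell (4 adjusted over the list alone; 0.000673) and 2 endothelial markers (6 adjusted over the list alone; 6.09e-05), each with an adjusted p of 0.637 with an estimated correlation. Lgals3, a lectin of macrophages, rose from 11.05 to 78.4 ± 13.9 CPM at 75 d and from 9.91 to 112 ± 37.3 at 150 d. Of 14 macrophage markers 2 rose at 150 d, Lgals3 and Cd68 (2 adjusted over the list alone; 0.0429, and adjusted p = 0.741 with an estimated correlation). Of 19 extracellular matrix genes 3 rose, Timp1 by 3.70 ± 0.74, Bgn by 2.23 ± 0.32 and Postn by 1.68 ± 0.34 (3 adjusted over the list alone; 0.00961, and adjusted p = 0.741 with an estimated correlation). Without SOD1G93A replicate 1 at 150 d the shift of the matrix list was lost (camera adjusted p = 0.769) and the macrophage list leaned downward (0.723).

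Among the other lists at 150 d, 2 of 8 tendon markers rose, Scx and Comp (2 adjusted over the list alone; camera adjusted p = 0.447), 1 of 12 fibroblast markers rose, Pi16, and 1 fell, Dcn (0.47). Dok7, which organises the receptor at the synapse, was 1 of 12 neuromuscular junction genes that rose (1 adjusted over the list alone; 0.359). Sdc4, a proteoglycan of muscle stem cells, was 1 of 7 satellite cell markers that rose (1 adjusted over the list alone; 0.447), and 1 of 13 clock genes fell (1 adjusted over the list alone; 0.305). No member passed among 8 smooth muscle (camera adjusted p = 0.106), 7 adipocyte (0.0788), 3 lymphocyte (0.586) and 5 sex-linked genes (0.34) or 5 erythrocyte genes (0.0362, and adjusted p = 0.741 with an estimated correlation). The erythrocyte shift was lost under the replicate block (0.0509), without SOD1G93A replicate 1 (0.0738) or 3 (0.0538) at 75 d and without replicate 2 at 150 d (0.0821). Vwf, Kdr, Pi16 and Cd68 were lost at 150 d without a batch term. Pi16 and Dcn were lost under the replicate block and without SOD1G93A replicate 3 at 75 d, and Pi16 (0.85) without SOD1G93A replicate 1 at 150 d. DESeq2 did not call Vwf, Cd68 or Pi16.

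In all, edgeR called 249 of 13125 genes at 75 d (192 higher, 57 lower), 1171 at 150 d (660 higher, 511 lower) and 2110 averaged over ages (1194 higher, 916 lower). The direction was shared by every SOD1G93A section against the wild type section of its age for 249 of 249 genes at 75 d and 1169 of 1171 at 150 d, and by every such difference at both ages for 1979 of the 2110. These tests rest on 1 wild type section per age. With the batch term, the fits without SOD1G93A replicate 1 or 2 at 150 d share 1 estimate at 75 d. It comes from replicate 1 at 75 d alone, so the 2 fits are not separate results. Likewise, the fits without replicate 1 at 75 d or replicate 2 at 150 d share 1 estimate at 150 d, which comes from replicate 1 at 150 d alone. In all these fits the residual spread comes from replicates 2 and 3 at 75 d alone. Without a batch term the counts were 160 and 648 at 75 d and 150 d, and DESeq2 called 255 and 715. At 75 d, leaving out SOD1G93A replicate 1, 2 or 3 at 75 d gave 1483, 568 and 141 genes, and leaving out replicate 1 or 2 at 150 d gave 1512 and 1519. At 150 d, leaving out SOD1G93A replicate 1 at 75 d gave 3170, replicate 3 at 75 d 632 and replicate 2 at 150 d 3219. Averaged over ages, leaving out replicate 3 at 75 d gave 1269 and replicate 2 at 150 d 4104.

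SOD1G93A at 150 d was then set against SOD1G93A at 75 d, which asks how the diseased muscle changes as it ages. Slow fibre genes were among the genes that rose. Myh7 went from 6.76 ± 4.70 CPM (SD, n = 3) to 214 ± 167 (SD, n = 2), Tnnc1, the slow troponin C, from 9.54 ± 1.26 to 103 ± 32.4, Tnni1 from 28.1 ± 16.6 to 184 ± 102 and Myh2 from 649 ± 77.7 to 3066 ± 74.0. Among the falls were Mettl21c, a methyltransferase of muscle, from 31.8 ± 12.3 to 6.21 ± 0.350 CPM, Tfrc, the transferrin receptor, from 114 ± 36.7 to 27.9 ± 0.870, and Smox from 42.9 ± 30.7 to 11.7 ± 3.33. Postn, a matrix protein of repair, rose by 1.81 ± 0.23 on the log2 scale, Comp by 1.90 ± 0.31 and Ccn2, a growth factor of fibrosis, by 1.85 ± 0.29, while the extracellular matrix list did not shift, with 2 of 19 genes higher and 0 lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.2).

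By edgeR Myh7 rose by 5.33 ± 0.24 (adjusted p = 3.52e-05), Tnnc1 by 3.45 ± 0.19 (8.09e-05), Tnni1 by 3.11 ± 0.22 (0.000462) and Myh2 by 2.26 ± 0.22 (0.00306). Within the first and the second batch the log2 differences were 5.53 and 5.17 for Myh7, 3.13 and 3.67 for Tnnc1, 3.58 and 2.76 for Tnni1 and 2.43 and 2.14 for Myh2. The only 150 d section of the second batch is the one with Xist transcripts, so there age and this trait cannot be told apart. Smox changed by -1.97 ± 0.31 (0.0288), with -2.45 and -1.38 within the batches. Amd1 stood at -1.52 ± 0.27 and did not pass (0.0525, with -2.0 and -0.96 within the batches), nor did Odc1 (0.15, 0.837), Chrna1 (0.22), Myog (0.56) or Myh4 (-1.65 ± 0.40, 0.173). With 1 section left out, Chrna1 ran from -0.27 to 0.84 and Myog from -0.13 to 1.41. The highest values came without SOD1G93A replicate 2 at 150 d, so their course with age depends on single sections. With the batch term, the fits without replicate 1 at 75 d or without replicate 1 at 150 d share 1 estimate, so they are not separate results. Amd1 passed in DESeq2 (-1.47), without the gene filter (-1.53), without wild type at 150 d (-1.52), without SOD1G93A replicate 1 (-1.0) or 2 (-1.66) at 75 d and without SOD1G93A replicate 1 (-1.0) or 2 (-2.02) at 150 d. Myh4 passed without the gene filter (-1.66), without SOD1G93A replicate 2 at 75 d (-1.91) and without replicate 2 at 150 d (-2.35).

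Of the 12 slow fibre genes 10 rose (12 adjusted over the list alone; median log2 2.14, camera adjusted p = 3.53e-112, and adjusted p = 0.0987 with an estimated correlation). Of the 22 denervation genes 1 rose (6 rose and 1 fell adjusted over the list alone; 6.47e-05, and adjusted p = 0.763 with an estimated correlation). Of the 14 fast fibre genes 0 passed (4 fell adjusted over the list alone; 1.22e-09, and adjusted p = 0.763 with an estimated correlation), and of the 19 glycolysis genes 0 (5 fell adjusted over the list alone; 1.05e-10, and adjusted p = 0.763 with an estimated correlation). Of the 27 polyamine genes 1 fell, Smox (2 adjusted over the list alone; 0.0324, and adjusted p = 0.763 with an estimated correlation). Markers of macrophages (0.000237) and fibroblasts (0.000358) shifted down as lists with no member past the threshold over all genes (adjusted p = 0.763 for each with an estimated correlation). Both shifts were lost without SOD1G93A replicate 2 at 150 d, the section with Xist transcripts, where the macrophage list leaned upward (camera adjusted p = 0.759) and the fibroblast list stood at 0.722. Without SOD1G93A replicate 1 at 75 d or replicate 1 at 150 d the shifts of the denervation (0.505 and 0.48), glycolysis (0.0535 and 0.0677) and polyamine lists (0.4 and 0.373) were lost, and that of the polyamine list also without a batch term (0.0851).

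In all 81 genes passed (64 higher, 17 lower). Xist was among them, with 0 UMIs in both SOD1G93A sections of the first batch, so its call rests on replicate 2 at 150 d alone, and it was lost in DESeq2 and without a batch term. DESeq2 called 85, of which 63 were among the 81. The count was 25 without a batch term, which lost Tnni1 (2.71), Sln (2.14), Tnnt1 (2.12), Smox (-1.86) and Ccn2 (1.66) among others. It was 379 and 231 without SOD1G93A replicate 1 or 2 at 75 d, and 392 and 992 without replicate 1 or 2 at 150 d.

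The interaction asks whether the genotype difference itself changed between 75 d and 150 d. It passed for Myh7 (log2 7.18 ± 0.77), Tnnc1 (3.72 ± 0.43) and Gm29521, a predicted transcript (-3.84 ± 0.44), each with an edgeR adjusted p of 0.0457. Myh7 had only 17 and 4 UMIs in wild type at 75 d and 150 d, so the size of its value is uncertain. Gm29521 lies outside the rule for naming genes and was chosen after its values were seen. It had 86 and 98 UMIs in wild type, 177, 48 and 76 in SOD1G93A at 75 d and 12 and 3 at 150 d. Amd1 (-1.30 ± 0.44, 0.996), Smox (-1.32 ± 0.51, 0.996), Odc1 (0.12, 0.998) and Myh2 (1.95 ± 0.41, 0.594) did not pass, so a change of their genotype difference with age was not shown. Without the gene filter Smox (-1.33) and Myh2 (1.95) passed, in DESeq2 Myh2 (1.96), without SOD1G93A replicate 2 at 150 d Amd1 (-1.80), Smox (-1.81) and Myh2 (2.13), and Myh2 also without replicate 1 at 75 d (1.83) or 150 d (1.83). The fits without either replicate 1 share 1 estimate, so they are not separate results.

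Of the 12 slow fibre genes 2 were higher in this test (11 adjusted over the list alone; camera adjusted p = 9.96e-55, and adjusted p = 0.107 with an estimated correlation). The 13 mitochondrially encoded mRNAs (7.21e-15) and the 9 Schwann cell markers (1.19e-06) shifted down with no member past the threshold over all genes (adjusted p = 0.737 for each with an estimated correlation). So did the 10 immediate early and heat shock genes (2 lower adjusted over the list alone; 1.56e-05, and adjusted p = 0.737 with an estimated correlation), a shift lost without SOD1G93A replicate 2 at 150 d (0.0865). Each wild type age rests on 1 section, and DESeq2 called 10 genes in place of 3. The 3 calls were lost without a batch term, with RLE size factors and without the mitochondrially encoded genes (0 genes each). Leaving out SOD1G93A replicate 1, 2 or 3 at 75 d gave 78, 22 and 6 genes, and replicate 1 or 2 at 150 d 92 and 321.

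Within each section, areas rich in Myh4 were set against areas poor in it, which asks what sets the fastest fibres apart, since these lose their nerve early in ALS. Amd1, Smox, Amd2 and Sms were among 5 of 25 polyamine genes that were higher in the Myh4-rich areas. As the mean of the group effects with equal weights, Amd1 was higher by 1.57 ± 0.14 on the log2 scale (SE, edgeR adjusted p = 1.64e-09). Smox was higher by 1.33 ± 0.11 (8.77e-11), Amd2 by 1.45 ± 0.23 (4.07e-05) and Sms, spermine synthase, by 0.70 ± 0.11 (1.94e-05). The effect of Amd1 differed between the genotypes, as given below. Mstn, the inhibitor of muscle growth, was higher by 1.88 ± 0.13 (1.2e-11), the calcium buffer Pvalb by 1.13 ± 0.07 and the fast fibre actinin Actn3 by 1.04 ± 0.08. The Myh4-poor areas were richer in Myl3, a slow light chain (-3.55 ± 0.12, 1.02e-19), in Ankrd2 and Csrp3, stretch-responsive proteins (-2.59 ± 0.19 and -2.56 ± 0.21), and in Fabp3, a fatty acid carrier (-1.21 ± 0.09).

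Of 25 polyamine genes 5 were higher and none lower (5 adjusted over the list alone; camera adjusted p = 0.00212, and adjusted p = 0.25 with an estimated correlation). All 12 fast fibre genes were higher (12 past; 1.14e-29, and adjusted p = 0.12 with an estimated correlation) and all 10 slow fibre genes lower (1.09e-49, and adjusted p = 0.016 with an estimated correlation, the 1 list that held). Of 48 oxidative phosphorylation genes 44 were lower (47 adjusted over the list alone; 7.24e-35, and adjusted p = 0.25 with an estimated correlation), as were 19 of 20 fatty acid oxidation genes (19 adjusted over the list alone; 1.33e-43, and adjusted p = 0.12 with an estimated correlation). Of 19 glycolysis genes 8 were higher and 2 lower (9 and 2 adjusted over the list alone; 6.18e-06, and adjusted p = 0.344 with an estimated correlation).

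Markers of other cells moved with these areas. Of 14 macrophage markers 7 were higher in the Myh4-rich areas (11 adjusted over the list alone; 2.25e-07, and adjusted p = 0.12 with an estimated correlation), with Mrc1 at 0.88 ± 0.15, and of 12 fibroblast markers 8 (1.83e-07, and adjusted p = 0.139 with an estimated correlation), with Pi16 at 0.94 ± 0.12. All 7 Schwann cell markers (1.39e-09, and adjusted p = 0.12 with an estimated correlation) and 8 of 10 endothelial markers (9 adjusted over the list alone; 1.83e-07, and adjusted p = 0.28 with an estimated correlation) were lower. The Myh4-rich spots held fewer UMIs in 6 of the 7 sections, as in wild type at 75 d with medians of 4884.5 and 9292. In all 1372 of 11590 genes passed (600 higher, 772 lower). The count was 734 without wild type at 75 d and 914 without wild type at 150 d, and DESeq2 called 535. Odc1 (0.41 ± 0.13, 0.0311) was lost in DESeq2, without wild type at 75 d (0.35) or 150 d (0.06), without SOD1G93A replicate 3 at 75 d (0.39) and without SOD1G93A replicate 1 at 150 d (0.24). Pi16 was lost without wild type at 75 d (0.26), and Mrc1 (0.48) with a fixed boundary at a Myh4 share of 50%.

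**Figure D4:**
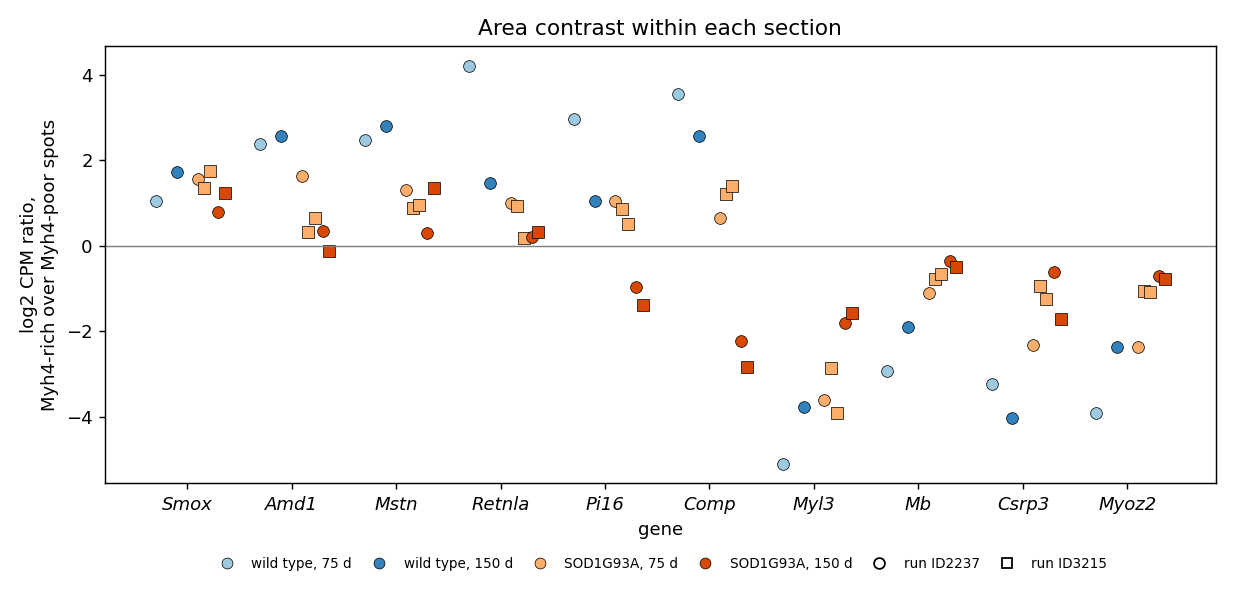
Log2 ratio of CPM in Myh4-rich over Myh4-poor areas for 10 genes, 1 point per section, by genotype and age. The fitted difference, averaged over the groups with equal weights, was 1.33 for Smox, 1.57 for Amd1 and -3.55 for Myl3.

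The difference between these areas was itself set between SOD1G93A and wild type. The areas are ranked within each section and cover unlike ranges: the median Myh4 share of the Myh4-rich spots was 95.7% and 90.2% in wild type at 75 d and 150 d and 49.5% and 51.2% in SOD1G93A at 150 d, near the 45.2% of the Myh4-poor spots of wild type at 75 d. Some contrasts were smaller in SOD1G93A. Retnla, made by alternatively activated macrophages, was higher in Myh4-rich areas by 2.85 in wild type and 0.49 in SOD1G93A (difference -2.36 ± 0.21, edgeR adjusted p = 1.47e-08), Mb, myoglobin, was lower by a log2 value of -2.42 in wild type and -0.64 in SOD1G93A (1.78 ± 0.15, 1.47e-08), and Amd1 was higher by 2.50 and 0.65 (-1.84 ± 0.28, 0.000104). The Odc1 contrast went from 1.03 in wild type to -0.22 in SOD1G93A (-1.25 ± 0.25, 0.00327) and that of Comp, a cartilage and tendon matrix protein, from 3.46 to -0.65 (-4.11 ± 0.43, 6.21e-07). The contrast of Smox, 1.40 in wild type and 1.27 in SOD1G93A, was not shown to differ (-0.12 ± 0.21, 0.868).

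Of 48 oxidative phosphorylation genes 28 had a higher contrast in SOD1G93A (45 adjusted over the list alone; camera adjusted p = 3.37e-34, and adjusted p = 0.257 with an estimated correlation). Of 14 macrophage markers 10 had a lower one (13 adjusted over the list alone; 5.8e-24, and adjusted p = 0.0818 with an estimated correlation), as had 10 of the matrix genes (11 adjusted over the list alone; 5.96e-16, and adjusted p = 0.0836 with an estimated correlation). The polyamine list did not shift, with 2 genes lower (2 adjusted over the list alone; 0.105). In all 414 genes passed (240 higher, 174 lower), 32 without wild type at 75 d, 623 and 270 without SOD1G93A replicate 1 or 3 at 75 d, 167 in DESeq2 and 125 with a fixed boundary at a Myh4 share of 50%. Without wild type at 75 d Retnla (-0.99) was lost, as were the macrophage genes C1qb (-1.03), Ccl6 (-0.94), Cd74 (-0.43) and Lgals3 (-0.68), the respiratory chain genes Ndufv1 (0.64) and Uqcrc1 (0.64) and the matrix genes Col1a1 (-0.83) and Lox (-1.33). The calls of these genes thus need that section. Whether its own values or the lost power of the comparison is behind this was not tested. Without wild type at 150 d Odc1 (-0.82) was lost.

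Between SOD1G93A at 150 d and 75 d the same contrast differed for matrix and connective tissue genes, among others. Col1a1, the main collagen, differed by -2.11 ± 0.20 (edgeR adjusted p = 1.04e-07), Comp by -3.62 ± 0.31 (1.76e-08), Pi16 by -1.96 ± 0.22 (4.04e-06) and Postn by -1.59 ± 0.25, so that they leaned more to the Myh4-poor areas at 150 d. Of the matrix genes 9 differed downward (12 adjusted over the list alone; camera adjusted p = 2.75e-23, and adjusted p = 0.104 with an estimated correlation), as did 5 macrophage markers (8 adjusted over the list alone; 2.15e-16, and adjusted p = 0.107 with an estimated correlation). Myl3 differed by 1.85 ± 0.23 (6.75e-06) and Mybpc2 by 1.11 ± 0.18 (0.000575). In all 116 genes passed (20 higher, 96 lower), 54 and 74 without SOD1G93A replicate 1 or 2 at 150 d and 34 in DESeq2. Mybpc2 was lost without replicate 2 at 150 d (0.83). With a fixed boundary at a Myh4 share of 50% the sign of Myl3 turned (-0.37).

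Areas rich in denervation transcripts were set against the other areas of the same SOD1G93A section, which asks what goes with denervation at the level of the tissue. These areas held more of Krt8 (log2 1.67 ± 0.11, 5 sections, edgeR adjusted p = 9.92e-08), Krt18 (1.47 ± 0.12, 4.47e-07), Uchl1, a deubiquitinase of neurons (1.40 ± 0.18, 1.63e-05), Spp1, a secreted cytokine (1.77 ± 0.28, 0.000101), and C3, a complement protein (1.69 ± 0.17). Odc1 was higher by 0.74 ± 0.11 (3.92e-05), whereas Smox was lower at -0.66 ± 0.14 (0.00169), and Amd1 did not pass (-0.41 ± 0.16, 0.095). They held less of mt-Atp8 (-1.48 ± 0.11, 2.34e-07), Lpl, which releases fatty acids from blood lipids (-1.30 ± 0.12, 5.86e-07), Eno3, muscle enolase (-1.09 ± 0.12, 4.42e-06), and Myh4 (-0.75 ± 0.16, 0.00255) and Myh1 (-0.84 ± 0.12, 2.81e-05). Myh4 was lower in each of the 5 sections, by a log2 ratio of -0.23, -0.25 and -0.51 at 75 d (replicates 1 to 3) and -1.10 and -1.70 at 150 d (replicates 1 and 2). Its share among the 4 myosin genes went the other way at 75 d, with medians over spots of 86.6% against 76.5%, 53.7% against 35.6% and 61.9% against 50.6% in areas rich in denervation transcripts and the other areas, and was lower in the former at 150 d (20.6% against 24.8% and 16.7% against 27.4%). The Myh4-rich areas likewise held a larger share of denervation UMIs than the Myh4-poor areas at 75 d (0.303% against 0.240%, 0.389% against 0.255% and 0.320% against 0.252%) and a smaller one at 150 d (0.446% against 0.457% and 0.247% against 0.375%). These shares were compared by value only.

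All 48 oxidative phosphorylation genes were lower (camera adjusted p = 5.47e-45), all 13 mitochondrially encoded mRNAs (6.43e-30), 18 of 19 glycolysis genes (19 adjusted over the list alone; 8.25e-21) and 18 of 20 fatty acid oxidation genes (19 adjusted over the list alone; 8.33e-20), each with an adjusted p of 0.181 with an estimated correlation. Of 14 macrophage markers 10 were higher (1.89e-07, and adjusted p = 0.201 with an estimated correlation), with Cd68 at 0.95 ± 0.22 and Cd74 at 0.89 ± 0.12. All 5 erythrocyte genes were lower (1.89e-07, and adjusted p = 0.181 with an estimated correlation), with Hbb-bs at -1.74 ± 0.28, as were 5 of 10 endothelial markers (7 adjusted over the list alone; 9.13e-05, and adjusted p = 0.181 with an estimated correlation). Of 24 polyamine genes 1 was higher and 4 lower (1 and 4 adjusted over the list alone; 0.385). In all 2038 of 11742 genes passed (821 higher, 1217 lower), 1321 without SOD1G93A replicate 3 at 75 d and 1181 in DESeq2. Cd68 was lost in DESeq2 and without SOD1G93A replicate 1 at 75 d (0.73), and Amd1 passed without that section (-0.62) and with spots scored without neighbours (-0.49). Spp1 was lost with the top 10% of spots (0.39).

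The same areas of the wild type sections, where the denervation list took 0.0766% and 0.0416% of the UMIs against 0.467% to 0.701% in SOD1G93A, differed in synaptic genes. Ache, acetylcholinesterase, was higher in the areas rich in denervation transcripts by 1.57 in wild type and lower, at -0.97, in SOD1G93A (difference -2.54 ± 0.46, edgeR adjusted p = 0.0143), and Ufsp1, a protease encoded next to it, went from 1.19 to -1.29 (-2.48 ± 0.32, 0.000514). Chrne, the adult receptor subunit, went from 1.88 to 0.19 (-1.68 ± 0.36, 0.039) and Etv5, a factor of synaptic nuclei, from 1.93 to -0.04 (-1.97 ± 0.38, 0.0237). Of 12 neuromuscular junction genes 4 had a lower contrast in SOD1G93A (7 adjusted over the list alone; camera adjusted p = 3.32e-09, and adjusted p = 0.347 with an estimated correlation). In all 67 genes passed (5 higher, 62 lower), 26 and 24 without SOD1G93A replicate 2 or 3 at 75 d, 37 in DESeq2 and 221 with spots scored without neighbours. Ache (-2.27), Etv5 (-1.55) and Chrne (-0.85) were lost without wild type at 150 d. Many of the 67 genes lost the call without that section, and many without wild type at 75 d. The result thus rests on each single wild type section. Etv5 and Chrne were lost without SOD1G93A replicate 2 (-1.91 and -1.69) or 3 (-1.92 and -1.58) at 75 d, and Chrne without SOD1G93A replicate 1 (-1.72) or 2 (-1.71) at 150 d. In SOD1G93A alone the lower Ache was lost in DESeq2 and without replicate 1 (-0.86) or 2 (-0.75) at 75 d.

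Denervation transcripts were spatially clustered in SOD1G93A. Moran's I of their share, at 1000 UMIs per spot, was 0.0626 and 0.0108 in wild type at 75 d and 150 d, 0.334 ± 0.0788 (SD, n = 3) in SOD1G93A at 75 d and 0.282 ± 0.0579 (SD, n = 2) at 150 d. Without thinning it was 0.203 and 0.168 in wild type and 0.632 and 0.478 in SOD1G93A. The list summed to 510 and 279 CPM in wild type and 2802 ± 44.0 and 3320 ± 801 in SOD1G93A, so that a wild type spot thinned to 1000 UMIs held less than 1 UMI of it on average, and the low wild type values do not show that patches were absent there. For the slow fibre list it was 0.293 and 0.261 in wild type, 0.281 ± 0.121 and 0.357 ± 0.0409 in SOD1G93A. At that depth Chrna1 was seen in 0.670% of spots in wild type at 75 d (exact Clopper-Pearson 95% interval 0.290 to 1.32) and 0.823% at 150 d (0.331 to 1.69). In SOD1G93A it was seen in 16.2%, 28.1% and 19.97% at 75 d and 33.8% and 20.9% at 150 d. Amd1 was seen in 10.1% and 8.11% of wild type spots, in 4.25%, 1.72% and 2.44% in SOD1G93A at 75 d and in 0.967% and 1.18% at 150 d. Myh2 was seen in 22.8% and 26.9% of wild type spots and in 84.9% and 89.4% in SOD1G93A at 150 d. Myh7 was seen in 5.22% and 26.3% of spots in SOD1G93A at 150 d and in 0 of the spots of wild type at 150 d (0 to 0.433).

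**Figure D5:**
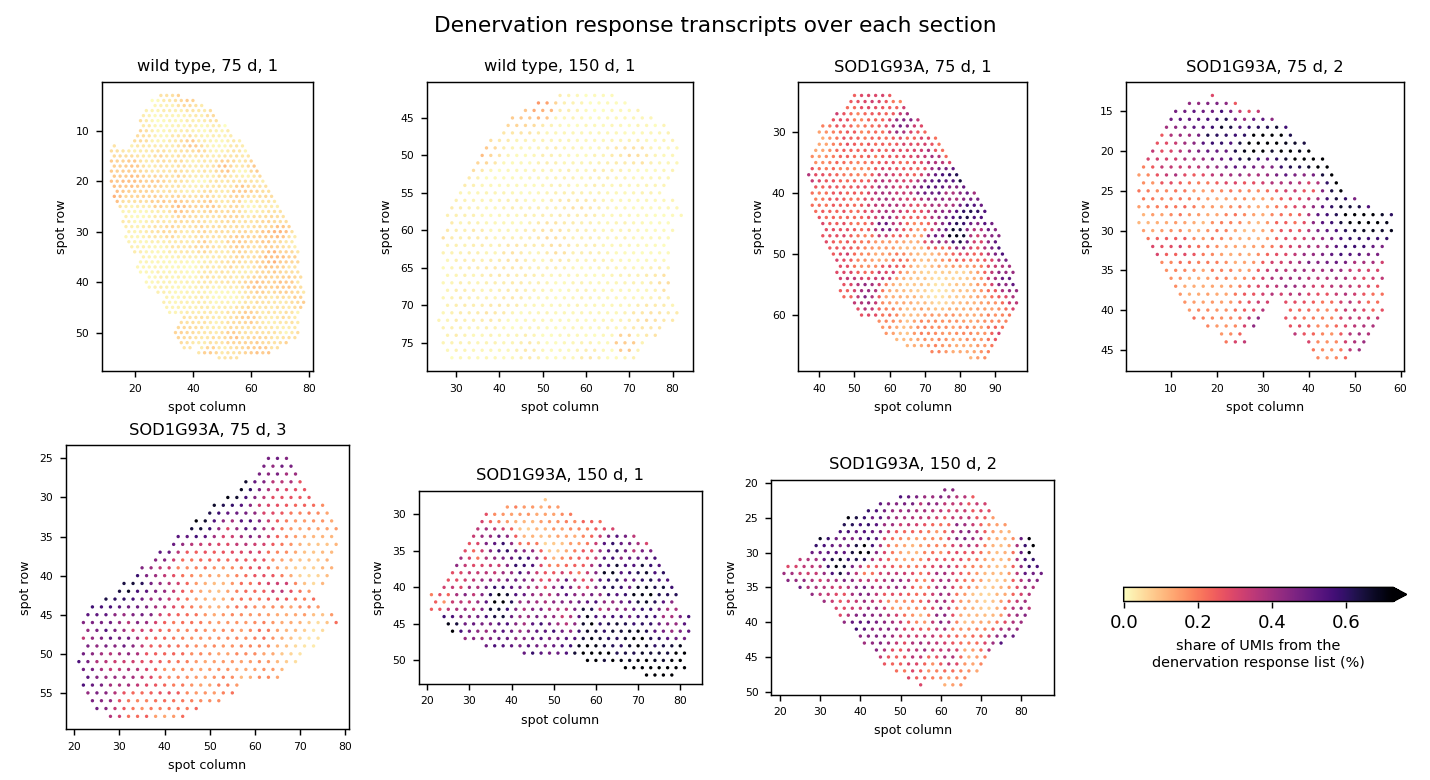
Map of each of the 7 sections with spots coloured by the percentage of UMIs from the denervation list in a spot and its neighbours, on a scale that stops at the 99th percentile. The SOD1G93A sections hold patches of high values (Moran's I without thinning 0.632 at 75 d and 0.478 at 150 d, against 0.203 and 0.168 in wild type).

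The wild type sections at 150 d and 75 d, 1 each, were compared by value only. Of 3919 genes with a mean of at least 20 CPM over the 2 sections, 14 at least doubled and 11 fell to 50% or less. Csrp3 went from 20.2 to 92.4 CPM, Ankrd2 from 49.4 to 135, and Cfd, an adipocyte protease, from 19.7 to 65.1. Retnla went from 274 to 79.98 CPM, Actc1, the cardiac actin, from 352 to 112, and the macrophage genes Ccl6 and Mrc1 from 42.0 to 12.9 and from 32.9 to 14.6. Ighg2c and Igkc, immunoglobulin chains of plasma cells, had 1 and 2 UMIs at 75 d and 597 and 289 at 150 d.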

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

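The tests on the Xist section, on the Amd2 copy and on the fibre share were chosen only after the result was seen. Results below stand here because the effect of a comparison differed between groups by a test of that difference. The interaction of genotype and age passed for 3 genes by edgeR, Myh7 (log2 7.18), Tnnc1 (3.72) and Gm29521 (-3.84). Myh7 had only 17 and 4 UMIs in wild type at 75 d and 150 d. The Myh4 area contrast differed between SOD1G93A and wild type for 414 genes and between SOD1G93A at 150 d and 75 d for 116 genes. The denervation area contrast differed between SOD1G93A and wild type for 67 genes. Many of these 67 lost the call without wild type at 75 d or at 150 d, while other genes gained it, so their count alone hides this change. Leaving out a section moved these counts to between 6 and 321 (3 genes), 32 and 623 (414 genes), 54 and 134 (116 genes) and 24 and 94 (67 genes). The sections behind the changes over 1.5 times were each of the 5 SOD1G93A sections for the 3 genes, wild type at 75 d (32) and SOD1G93A replicates 1 (623) and 3 (270) at 75 d for the 414, SOD1G93A replicates 1 (54) and 2 (74) at 150 d for the 116, and replicates 2 (26) and 3 (24) at 75 d for the 67. For the 3 genes the values without replicates 1 to 3 at 75 d were 78, 22 and 6, and without replicates 1 and 2 at 150 d 92 and 321.

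Slow fibre genes were higher in SOD1G93A at 150 d than at 75 d. A slow muscle or area that covers a minority of the spots, present in the 150 d sections alone, would leave the median spot alike. The lower of their median spot Myh2 shares was 5.184 times the highest at 75 d (16.5% and 19.6% against 0.385%, 3.18% and 2.45%). For Myh2 this argues against such a small area. A slow area over most of a section would raise the median spot too, so the test cannot decide on it. For Myh7 a small slow area cannot be told apart. The top 10% of spots held 80.32% of its UMIs in 1 section at 150 d and 45.82% in the other, values that meet neither of the bounds set. The section with Xist transcripts does not carry the rise alone, because within the first batch, free of Xist, the list's median log2 difference was 2.131 with 11 of 12 members higher. The difference in age that the design names stays open and was not tested apart from a loss of the fastest fibres or a different plane of section, which would need fibres counted by type in matched sections.

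Amd1 and Smox were lower in SOD1G93A than in wild type, and both were richer in Myh4-rich areas. In spots with a Myh4 share of 50% to 80% the highest SOD1G93A section still had 0.3043 times the Amd1 CPM of the lowest wild type section, which argues against fewer Myh4-rich areas as the whole cause for Amd1. For Smox the same ratio was 1.107, from 61.3 CPM in SOD1G93A replicate 1 at 75 d and 55.4 in wild type at 150 d. Fewer Myh4-rich areas would give such a ratio, but these sections differ in age. In those spots SOD1G93A had 61.3, 33.1 and 32.4 CPM of Smox at 75 d, against 100 in wild type of that age. At 150 d it had 29.1 and 14.0 CPM (31 and 9 UMIs), against 55.4 in wild type. Within each age Smox was thus lower in SOD1G93A at a like Myh4 share, by value only. How much of its fall fewer Myh4-rich areas account for remains open. The CPM of these spots are without TMM scaling. Such scaling would lower both ratios, as the factors were 0.847 and 0.709 in wild type and 0.921 to 1.22 in SOD1G93A. A shift of reads from Amd1 to Amd2 would raise Amd2, which instead changed by -2.357 averaged over ages.

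Mitochondrially encoded mRNAs were lower in SOD1G93A than in wild type. A difference in UMIs per spot is argued against by spots of 5000 to 15000 UMIs, where the lowest wild type section still lay 7.963 percentage points above the highest SOD1G93A section (SD of the SOD1G93A sections 2.317). A lower share of muscle fibre would raise the markers of other cells whose own number is unchanged. Averaged over ages, 2 of 9 marker lists, Schwann cell and endothelial, moved down with no member up. The number of these cells was not measured, so their markers cannot decide on the share of muscle fibre. The difference in genotype stays open, since the share of muscle fibre was not settled. RNA quality and the mitochondrial content of the fibre types in each section were not tested. Both wild type sections lay in the first batch, and within that batch the mitochondrial share was 32.8% and 42.6% in wild type and 25.3% and 23.3% in SOD1G93A.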

How the results depend on the processing

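All alternatives were planned. Of the 284 pairs of a gene and a comparison past the threshold that were examined under the alternatives, 110 lost the call under at least 1 alternative and 2 turned in direction (Myl3 and Myl2 under a fixed Myh4 share). Over 4324 values under alternatives, 268 lost the call and 56 gained it. No call was lost without the gene filter (284 of 284 kept) or with all spots under tissue or a minimum of 1000 UMIs per spot (146 of 146 each), 277 of 284 were kept with RLE size factors, 138 of 142 without the mitochondrially encoded genes, 241 of 274 in DESeq2, 105 of 146 without a batch term, 110 of 146 under the replicate block and 236 of 284 without SOD1G93A replicate 3 at 75 d. Limits are the 1 wild type section per age, the 2 residual degrees of freedom and the depth of the shallowest section. In the fits of whole sections, leaving out a SOD1G93A section lowers the residual degrees of freedom. Leaving out a wild type section there also removes its group term and does not change them. Fewer residual degrees of freedom alone would lower the power, so they do not account for counts that rose when a section was left out. Without SOD1G93A replicate 1 at 75 d, or replicate 1 or 2 at 150 d, the residual spread there comes from replicates 2 and 3 at 75 d alone. These were the most alike replicates (chi-square per degree of freedom 14.1, against 28.5 to 49.4 for the other pairs). Higher counts and calls gained in these fits are thus not shown to be stronger evidence. The cause of the changes given here was not tested. Without a wild type section the contrasts of whole sections that use it cannot be formed.

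In DESeq2 the count was 715 for SOD1G93A against wild type at 150 d, 1053 averaged over ages and 10 for the interaction (1171, 2110 and 3 by edgeR). It was 535 for Myh4-rich areas, 167 for their difference by genotype and 34 by age, 1181 for areas rich in denervation transcripts and 37 for their difference by genotype. With RLE size factors, without a batch term and without the mitochondrially encoded genes the interaction count was 0 (edgeR; 492 genes at an unadjusted p under 0.05 and 10 by DESeq2 with the batch term and all genes). Without the gene filter the count was 493 for SOD1G93A at 150 d against 75 d, 1147 and 2313 against wild type at 75 d and 150 d, 91 for the interaction, 176 for the Myh4 areas by age and 282 for the denervation areas by genotype; more genes were tested there. Without a batch term it was 25, 160 and 648 for SOD1G93A at 150 d against 75 d and against wild type at 75 d and 150 d. With a fixed Myh4 share it was 827 for Myh4-rich areas and 125 for their difference by genotype, and with spots scored without neighbours 221 for the denervation areas by genotype.

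With the replicate number as a block, which leaves 1 residual degree of freedom, the count was 58 for SOD1G93A at 150 d against 75 d, 129 and 582 against wild type at 75 d and 150 d, 1226 averaged over ages and 4 for the interaction, with 14, 12, 17, 14 and 13 gene lists shifted. The block gives SOD1G93A replicate 3 at 75 d, the only section with that number, a term of its own. It thus repeats the fit without that section and is not a separate check. Myh7 at 75 d stood at -0.16 under the block. The block ended 36 calls of the examined genes, among them Odc1 (1.65) and Sod1 (2.37) at 75 d and Myh2 (1.89), Fbxo32 (1.07), Cox7b (-1.66), Cycs (-1.66) and Map1lc3a (1.81) at 150 d.

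With an estimated correlation 0 of the 30 gene lists shifted in each of the 5 comparisons of whole sections by camera, and fry called 0 in each (12, 11, 16, 14 and 13 by camera with the preset correlation). With an estimated correlation camera rests on the 2 residual degrees of freedom, so hardly any list could pass. This does not show that the lists did not shift. In the area comparisons, 1 list held for Myh4-rich areas and 0 for the other 4 (16, 15, 17, 18 and 16 with the preset; fry called 8, 2, 0, 15 and 0).

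Leaving out each section in turn gave 68 to 992 genes for SOD1G93A at 150 d against 75 d, 141 to 1519 and 632 to 3219 against wild type at 75 d and 150 d, 1269 to 4104 averaged over ages and 6 to 321 for the interaction. It gave 734 to 1345 genes for Myh4-rich areas, 32 to 623 for their difference by genotype and 54 to 134 by age, 1321 to 2349 for areas rich in denervation transcripts and 24 to 94 for their difference by genotype. In the 5 comparisons of whole sections the lowest count came without SOD1G93A replicate 3 at 75 d and the highest without replicate 2 at 150 d.

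Signs turned for log2 values not past the threshold in the main fit. The ranges below give log2 values only, and some of their ends may have passed. With 1 section left out, for SOD1G93A at 150 d against 75 d, Chrna1 ran from -0.27 to 0.84, Myog from -0.13 to 1.41, Fbxo32 from -0.41 to 0.049 and Trim63 from -0.98 to 0.021. The sign turned without SOD1G93A replicate 1 at 75 d and without replicate 1 at 150 d (Chrna1 -0.27 in both), fits that share 1 estimate. The opposite ends of Chrna1, Myog and Trim63 came without replicate 2 at 150 d. Against wild type at 75 d, Myh2 ran from -0.18 to 0.11 (turned without SOD1G93A replicate 1 at 75 d) and Myh7 from -0.21 to 0.31 (turned without replicate 3 at 75 d and without either section at 150 d). Against wild type at 150 d, Myh1 ran from -0.051 to 0.036 (turned without replicate 1 at 150 d). Myh1 stood at 0.014 there without the gene filter, and without a batch term at -0.051 at 75 d and -0.12 averaged over ages. For Myh4-rich areas, Sod1 ran from -0.081 to 0.044 (turned without wild type at 75 d and SOD1G93A replicate 2 at 150 d) and stood at 0.00106 in DESeq2, 0.00107 with RLE size factors and 0.0144 with the outer 25% of spots on each side. Sat1 ran from -0.35 to 0.11 and Srm from -0.15 to 0.22 (both turned without wild type at 150 d, and Srm, at -0.024, without SOD1G93A replicate 1 at 150 d). For their difference by genotype, Smox ran from -0.48 to 0.22 and Sms from -0.68 to 0.018 (both turned without wild type at 150 d, and Smox, at 0.051, without SOD1G93A replicate 1 at 150 d). In areas rich in denervation transcripts Sat1 ran from -0.12 to 0.03 (turned without SOD1G93A replicate 2 at 75 d, 0.0298) and stood at 0.0313 with the top 10% of spots. Past the threshold, Myl3 stood at -0.37 and Myl2 at -0.56 for the Myh4 areas by age with a fixed share.

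Moran's I of the denervation list depended on depth. Without thinning it was 0.203 and 0.168 in wild type at 75 d and 150 d and 0.632 and 0.478 in SOD1G93A, and at 500 UMIs per spot it was 0.237 and 0.168 in SOD1G93A. For the slow fibre list it was 0.437 in wild type at 150 d and 0.493 in SOD1G93A at 75 d without thinning.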

Other observations

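The tests that follow were planned, and the genes were named by the rule. Among 13 genes of the circadian clock, 4 fell in SOD1G93A averaged over ages and none rose (2 rose and 5 fell adjusted over the list alone), and the list as a whole did not shift (camera adjusted p = 0.135). Bhlhe41, a repressor of the clock, stood at 61.0 and 52.3 CPM in wild type at 75 d and 150 d and at 31.0 ± 1.42 (SD, n = 3) and 23.3 ± 5.37 (SD, n = 2) in SOD1G93A (log2 -0.92 ± 0.17, edgeR adjusted p = 0.01). Ciart (-1.18 ± 0.32, 0.0369), Per2 (-0.82 ± 0.21, 0.0299) and Per3 (-0.69 ± 0.18, 0.0321), repressors of the same loop, were lower too. The time of day of collection was not used here, and it sets the level of these genes. Ciart, Per2 and Per3 were lost without a batch term (-0.86, -0.52 and -0.20), under the replicate block (-1.18, -0.82 and -0.69) and in DESeq2. The fit without SOD1G93A replicate 3 at 75 d, which the block repeats, lost the same genes (-1.18, -0.82 and -0.69). Ciart was lost without replicate 1 at 75 d (-0.81), and Per2 and Per3 without replicate 1 at 150 d (-0.69 and -0.53).

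Averaged over ages, some genes of the integrated stress response rose. Atf3, a stress-induced transcription factor, rose by 3.53 ± 0.73 (edgeR adjusted p = 0.0149) and Mthfd2, a mitochondrial folate enzyme, by 1.85 ± 0.51 (0.0405), and 3 of 15 genes of the list rose (3 adjusted over the list alone; camera adjusted p = 0.184). Mt2, a metallothionein, rose by 2.74 ± 0.66 (0.026). At the synapse Dok7 rose by 1.27 ± 0.22 (0.00726) and Rapsn, which clusters the acetylcholine receptor, by 1.01 ± 0.20 (0.0117), 2 of 12 neuromuscular junction genes (camera adjusted p = 0.434). Mt2 was lost in DESeq2 and Mthfd2 (0.66) without SOD1G93A replicate 1 at 150 d.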
